A study of Mus musculus with 12 samples.

How the data were processed

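Hearts of 12 mice in 4 groups were compared, with 1 array per heart, as the labels state them. The deposited table of non-normalized values gives, for each of 45281 probes and each array, a probe signal (intensity, linear scale, neither normalized between arrays nor background-subtracted) from biotin-labelled cRNA. Beside each signal it gives a detection p-value, per the file headers, which compares the probe with the negative control beads of its array. A second table deposited by the authors holds log2 values, quantile normalized in 3 separate sets of arrays (5, 3 and 4 arrays), as found from the values. The method of that normalization and the reason for the sets are not stated, and the files do not name the chip of an array. No genome came with the series, so positions are not given.

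Probe signals were background corrected and quantile normalized over all 12 arrays with neqc of limma (version 3.58.1, R 4.3.3), with the background taken from the detection p and an offset of 16. A probe entered if its detection p was under 0.05 on at least 2 arrays, which left 20312 probes. Gene symbols came from the reference table for the platform. Of all probes, 34885 had 1 symbol, 18 had several and 10378 had none, and the latter kinds were kept under their probe name. A gene was represented by its probe with the highest mean, which gave 14240 genes, called so below, of which 11009 had a symbol. On the 11 arrays without the doubted library there were 14116.

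One linear model with a mean per group was fitted to all arrays with limma's lmFit and eBayes, and 5 contrasts were taken, VEGF-B within each genotype, the deletion within each virus, and their interaction. P-values were adjusted by Benjamini-Hochberg over all genes within a contrast, and a gene was called at an adjusted p under 0.05. All tests are two-sided. Genes were named by a rule fixed in advance. It takes all VEGF ligands and receptors. For each contrast it takes the 10 highest and 10 lowest called genes whose values do not overlap between the groups compared, filled up to 20 with the smallest p where fewer passed, and up to 4 members of smallest p of each list that is described. The probes ILMN_2476405 and ILMN_2772264, the genes Ern1, BC028528, Cntn3 and Rbp7, and Dip2c and Csprs where they fall outside that rule, were named after their values were seen. So were Ciita, Cd3g and H2-Ab1. Where the lower group was not detected, a change is given as at least the fold over the detection floor.

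For gene lists, 42 were fixed, of pathways, functions and cell type markers, and 40 had measured genes. The mesothelium and lung epithelium lists had none. Each list was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the 40 lists within a contrast, and again with a correlation estimated per list, and with fry. Genes of a list were also counted after adjustment over the list alone. Some lists share genes, such as Hey1, Pdgfb and Col4a1. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The fits that use the authors' normalization sets, and the fit without the doubted library as a second account, were chosen afterwards. So were the tests that weigh explanations of flagged patterns, apart from the counts of other splits.

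The likeness of the responses was measured as a correlation across genes. Where the comparisons share arrays, the value for unchanged groups was simulated 100 times against the same controls. Differences of list scores were tested by exact permutation within genotype. The pipeline was tested on simulated data with 200 changed genes of 14240. At a log2 change of 1 the calls recovered 94.0% of those genes for VEGF-B in wild type, 98.5% for VEGF-B in deleted hearts, 94.0% and 91.0% for the deletion with scramble and with VEGF-B, and 67.2% for the interaction. At a change of 0.5 the shares were 25.4%, 35.8%, 26.9%, 22.4% and 2.99%. Unchanged genes called by mistake numbered 10, 15, 10, 7 and 3. The simulated noise was independent between genes and arrays, with no difference between sets and no array apart. The shares therefore hold for such arrays and not for the real ones. Alternatives to the background correction, offset, scaling, filter, choice of probe, variance model, array weights, threshold, arrays in the fit and blocks were run, with each array left out in turn. Similar replicate numbers in different groups do not pair the hearts by anything stated in the labels. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.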

Results

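Transcripts were measured in the hearts of 12 adult male C57Bl/6J mice on bead arrays, with 1 array per heart. The series crosses a genotype with a virus. VEGFR1, encoded by Flt1, is a receptor that binds VEGF-A, VEGF-B and placental growth factor. It was deleted from endothelial cells by a tamoxifen-inducible Cre recombinase under the Cdh5 promoter. An adeno-associated virus (AAV), injected intraperitoneally, carried VEGF-B or a scramble control. The groups held 3 wild-type hearts with scramble virus (WT_Scramble), 3 VEGFR1-deleted hearts with scramble virus (VEGFR1del_Scramble), 2 wild-type hearts with VEGF-B virus (WT_VEGFB) and 4 VEGFR1-deleted hearts with VEGF-B virus (VEGFR1del_VEGFB). The median signal per array ran from 98.7 to 111.5, and 16685 to 18210 probes per array were detected. The number of hearts limits the precision, and each value below is a log2 signal or a log2 fold change with its standard error (SE) from a model that shares the spread over the 4 groups. On the first principal component, which held 39.5% of the variance, the WT_Scramble arrays lay at -26.4 to -21.4, the WT_VEGFB arrays at 1.80 and 3.91, and the VEGFR1del_VEGFB arrays at 17.8 to 25.4.

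Flt1 itself was read first, since its signal shows whether the deletion can be seen on each array (probe ILMN_1227926; whether the probe lies in the deleted part of the gene is not known). Flt1 gave 10.87 ± 0.07 (SD, n = 3) in WT_Scramble, 11.37 ± 0.20 (SD, n = 2) in WT_VEGFB and 9.19 ± 0.26 (SD, n = 4) in VEGFR1del_VEGFB. In VEGFR1del_Scramble, replicates 1 and 2 gave 8.19 and 8.46, and the library labelled VEGFR1del_Scramble replicate 3 gave 11.56, above every other array. A second Flt1 probe, ILMN_2732721, was detected on this library and on all 5 wild-type arrays, and on none of the other 6 VEGFR1-deleted arrays. On the first principal component this library lay at 3.75, and replicates 1 and 2 of its group lay at -11.1 and -10.3. It was kept under its label, and each comparison that uses VEGFR1del_Scramble is also given on the other 11 arrays, a choice made after the values were seen. The Vegfb probe (ILMN_2450384) did not differ with the VEGF-B virus in either genotype (log2 fold change -0.04, SE 0.11, adjusted p = 0.921 in wild type and -0.12, SE 0.09, adjusted p = 0.495 in VEGFR1-deleted hearts, limma). Whether this probe can read the transcript of the virus is not known, so the expression of the transgene was not measured here.

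**Figure D1:**
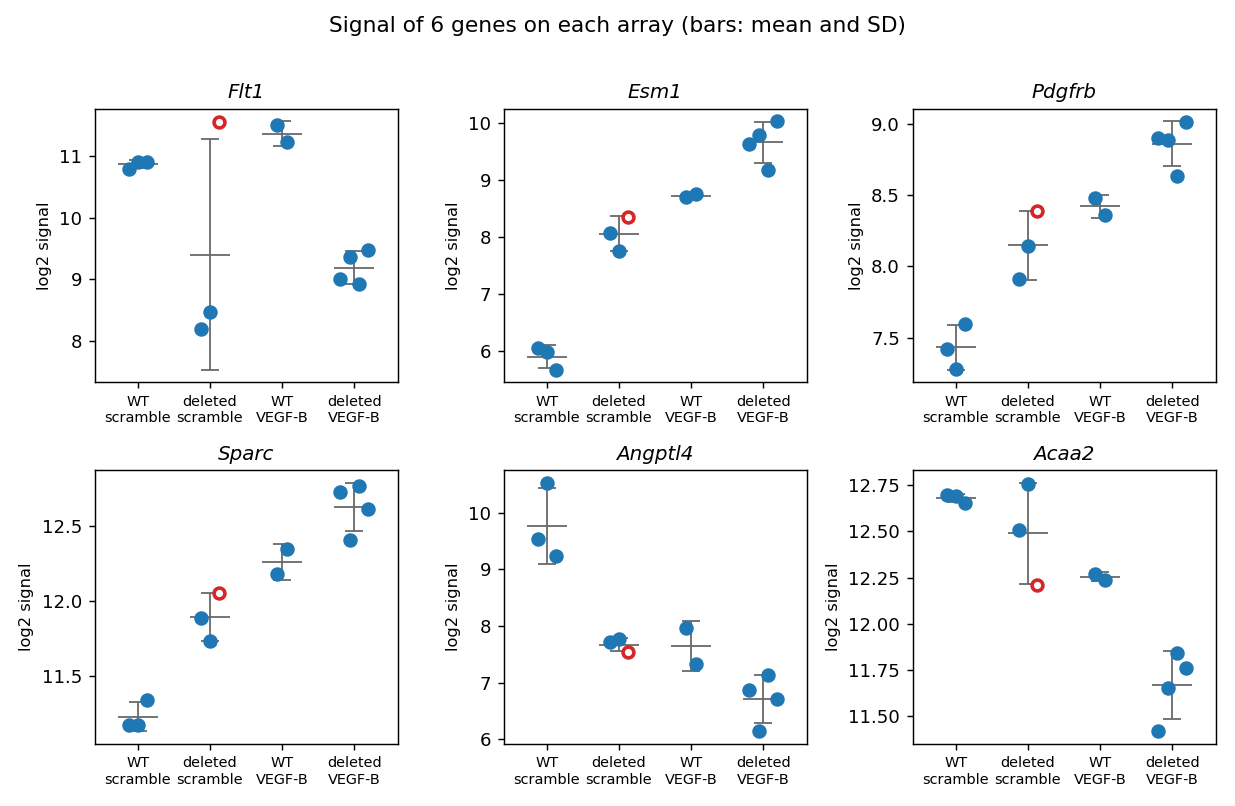
Log2 signal of Flt1, Esm1, Pdgfrb, Sparc, Angptl4 and Acaa2 on each of the 12 arrays by group, with the mean and SD of each group as bars; the open red circle is the library labelled VEGFR1del_Scramble replicate 3. Its Flt1 value of 11.56 lies above every other array, and Esm1 is lowest on the 3 WT_Scramble arrays, where Angptl4 is highest.

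The effect of VEGF-B was asked first in wild-type hearts (WT_VEGFB, n = 2, against WT_Scramble, n = 3). Genes of sprouting endothelium were higher with VEGF-B. Esm1, a proteoglycan secreted by endothelial tip cells, was 7.08-fold higher (log2 fold change 2.82, SE 0.22, adjusted p = 0.000156, limma). Stc1, a secreted glycoprotein, rose by 2.21 (SE 0.24), the matricellular gene Ccn5 by 1.94 (SE 0.21), Ssu2 by 1.85 (SE 0.19), the Notch target Hey1 by 1.52 (SE 0.24) and the chemokine receptor Cxcr4 by 1.34 (SE 0.17). The fall was largest for Angptl4, a secreted inhibitor of lipoprotein lipase, at 4.35-fold (log2 fold change -2.12, SE 0.34, adjusted p = 0.0145). Next came the mitochondrial carrier Ucp3 (-1.76, SE 0.34) and Pdk4, a kinase that restrains glucose oxidation (-1.49, SE 0.34). In all, 284 of 14240 genes passed an adjusted p of 0.05, 249 higher and 35 lower. By rule, genes were named by the size of their change only where WT_VEGFB and WT_Scramble values did not overlap. The largest rises and falls given are the largest among such genes. The other genes named among the largest rises were Mest, H2ac12, Exoc3l and Gdf10, between 1.30 and 1.45. The other large falls were Ccdc141 at -1.22, Zbtb38, Csnk2a1, Inhba, Tacc2, Relt and Tbc1d4, the last at -0.78. The co-receptor Nrp1 rose by 0.55 (SE 0.13, adjusted p = 0.0429), and the other 9 measured VEGF ligands and receptors, Vegfa, Vegfb, Vegfc, Vegfd, Pgf, Flt1, Kdr, Flt4 and Nrp2, did not pass, at -0.22 to 0.72. Kdr lay near background on all arrays.

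By gene list, 18 measured tip cell and sprouting genes had a median log2 fold change of 0.82 (camera adjusted p = 2.16e-20). Of these, 10 rose over all genes tested and 16 when adjusted over the list alone, among them Mcam (1.21) and Nid2 (1.17). The list held with an estimated correlation (adjusted p = 0.0493), as did Notch pathway (median 0.63, 6 of 11 rose), pericyte (0.69, 6 of 10 rose), capillary endothelium (0.50, 2 of 7 rose) and venous endothelium (0.39, 2 of 6 rose). Adjusted over the list alone, 7, 10, 5 and 3 genes of these 4 lists rose. Nrarp, which is induced by Notch, rose by 1.13, the pericyte receptor Pdgfrb by 0.99 and the apelin receptor gene Aplnr by 0.98. The general endothelial markers had a median of 0.62, with all 22 above 0 and 11 past the threshold (16 adjusted over the list alone), as for Cd93 (0.87) and Emcn (0.73). This call was lost with an estimated correlation (adjusted p = 0.0693 with an estimated correlation). Basement membrane genes had a median of 0.54, and 5 of 15 rose (11 adjusted over the list alone), as for Sparc (1.03) and Col4a1 (0.92). For them the adjusted p = 0.0653 with an estimated correlation. Both lists held without the library labelled VEGFR1del_Scramble replicate 3 (adjusted p = 0.0115 with an estimated correlation), and so did the 5 lists above. Fatty acid oxidation genes had a median of -0.20, and 2 of 21 fell (5 adjusted over the list alone), Ucp3 and Pdk4 (adjusted p = 0.353 with an estimated correlation). These 2 genes are not enzymes of the oxidation itself. Ventricular cardiomyocyte markers had a median of -0.03 and did not pass.

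Another 8 lists passed in wild-type hearts with the preset correlation and not with an estimated one. Cell cycle genes had a median of 0.26 (1 of 21 rose, Mcm6 by 0.73) and endothelial paracrine factors one of 0.24 (2 of 11 rose, Pdgfb by 1.09 and Nos3 by 0.82). Arterial endothelium had a median of 0.23 (1 of 7 rose, Hey1). For these 3 lists the adjusted p = 0.0934 with an estimated correlation. Interstitial matrix genes had a median of 0.29 with none of 18 past (adjusted p = 0.281 with an estimated correlation). Interferon response (median 0.45) and antigen presentation (0.52) held no gene past the threshold, and for both the adjusted p = 0.499 with an estimated correlation. Immediate early genes (0.45, adjusted p = 0.637 with an estimated correlation) and neutrophil markers (0.45, adjusted p = 0.147 with an estimated correlation) held none either. Without WT_VEGFB replicate 1 the calls of interferon response (adjusted p = 0.766), antigen presentation (0.0776) and neutrophil were lost. Without WT_VEGFB replicate 2 those of paracrine factors (0.110), arterial endothelium (0.106) and immediate early genes were lost, and without WT_Scramble replicate 1 those of immediate early genes and neutrophil, with adjusted p up to 0.686 and 0.168.

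The number of genes in wild-type hearts fell with any 1 of the compared arrays left out, where the power of the fit is lower as well. It was 161, 27 and 53 without WT_Scramble replicates 1, 2 and 3, 12 and 4 without WT_VEGFB replicates 1 and 2, where the lone array is assumed to vary like those of the other groups, and 397 without the library labelled VEGFR1del_Scramble replicate 3, of which 283 were among the 284. Of 39 calls named for this comparison, Esm1, Ccn5 and Ssu2 held without any 1 array, and with BC028528 they were the 4 without WT_VEGFB replicate 2. The authors normalized the arrays in 3 sets. Set 1 held the WT_Scramble arrays and VEGFR1del_Scramble replicates 1 and 2. Set 2 held the library labelled VEGFR1del_Scramble replicate 3 and both WT_VEGFB arrays, and set 3 the VEGFR1del_VEGFB arrays. If the sets were also batches of arrays, which is not stated, set and virus coincide on all arrays but that library, so the effect of VEGF-B and the set cannot be told apart. With the set as a fixed block on sets 1 and 2, where that library alone links them, 3 features were called, Flt1 (-2.73), the unnamed probe ILMN_2476405 (4.32) and Esm1 (2.37, SE 0.26, adjusted p = 0.0341), and of these Esm1 was among the 284. The values of Flt1 and of that probe are not read as effects of VEGF-B. Both had wild-type-like signals on the linking library. Between the groups themselves Flt1 gave 0.50, and the probe lay at 4.66 in WT_Scramble and 4.60 in WT_VEGFB. All values of this fit rest on the label of that library in the same way. Angptl4 then gave -1.92 (adjusted p = 0.641), the tip cell list a median of 0.38 (adjusted p = 1.05e-05) and fatty acid oxidation 0.04 (adjusted p = 0.790).

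The same question was asked in VEGFR1-deleted hearts (VEGFR1del_VEGFB, n = 4, against VEGFR1del_Scramble, n = 3). At the preset correlation fatty acid oxidation genes were lower and matrix, endothelial and secretory stress genes higher with VEGF-B, and none of these lists held with an estimated one (adjusted p = 0.0702 to 0.113 with an estimated correlation). Acaa2, the thiolase of mitochondrial fatty acid oxidation, fell by 0.82 (SE 0.13, adjusted p = 0.0111, limma), and the acyl-CoA thioesterase Acot1 by 2.01 (SE 0.30, adjusted p = 0.00922). Esm1 rose by 1.60 (SE 0.19, adjusted p = 0.00474) and Sdf2l1, a chaperone of the endoplasmic reticulum, by 1.61 (SE 0.22, adjusted p = 0.00834). Among genes of immune cells, S100a8 rose by 1.60 (SE 0.32), S100a9 by 1.36 (SE 0.22), at least 2.31-fold, the chemokine Ccl5 by 1.42 (SE 0.37) and the receptor Fcgr4 by 1.17 (SE 0.30). In all, 656 genes passed, 401 higher and 255 lower. Genes were again named by the size of their change only where the values of the 2 groups did not overlap. Without the library labelled VEGFR1del_Scramble replicate 3, 1031 passed, 665 higher and 366 lower, and 569 of them were among the 656. Without it the changes were -0.96 for Acaa2, -2.31 for Acot1, 1.75 for Esm1 and 1.82 for Sdf2l1, and Ccl5 (1.54, adjusted p = 0.0522) did not pass. The other large rises were Stc1 (1.48), Adamtsl2 (1.22), Lman1l (1.21) and the basement membrane collagen Col18a1 (1.18). The other large falls were Spon2, Pdk4, Ucp3, Lgals4, Kcnv2, the lipase Ces1d, the muscle fructose bisphosphatase Fbp2, Retnla and Ano10, between -1.50 and -1.09. Without that library Spon2 gave -1.31 (adjusted p = 0.0546).

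Of 21 fatty acid oxidation genes, 12 fell over all genes and all 21 when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 5.82e-16, and -0.56 without the doubted library, with 17 past), as for Acadl (-0.50) and Eci1 (-0.49). Oxidative phosphorylation had a median of -0.15, and none of 29 passed. Tricarboxylic acid cycle had a median of -0.21, and 1 of 10 fell, Mdh2 by 0.35 (2 adjusted over the list alone). Tip cell and sprouting genes had a median of 0.64 (0.82 without that library), and 13 of 18 rose (14 adjusted over the list alone), as for Unc5b (0.97), Mcam (0.94) and Igfbp3 (0.92). Endothelial markers had a median of 0.48 (0.60 without it), and 14 of 22 rose (17 adjusted over the list alone), as for Vwf (0.80) and Cdh5 (0.76). Basement membrane genes had a median of 0.51 (0.55 without it), and 10 of 15 rose (10 rose and 1 fell adjusted over the list alone). Interstitial matrix genes had a median of 0.53 (0.59 without it), and 4 of 18 rose (16 adjusted over the list alone), as for Loxl1 (0.47) and Bgn (0.45). Fetal and hypertrophic heart genes had a median of 0.43 (0.48 without it), and 2 of 10 rose (6 adjusted over the list alone), Nppa by 0.98 and Ankrd1 by 0.51. Unfolded protein and heat shock genes had a median of 0.31 (0.41 without it), and 3 of 16 rose (6 adjusted over the list alone), as for Pdia4 (1.09) and Hsp90b1 (0.76). With an estimated correlation none of the 21 lists that passed in this comparison held. For fatty acid oxidation, oxidative phosphorylation, tip cell, endothelial, basement membrane, interstitial and fetal genes the adjusted p = 0.0702 with an estimated correlation, for the tricarboxylic acid cycle 0.163 and for the unfolded protein list 0.113. On the 11 arrays without the doubted library 3 lists held, tip cell and basement membrane genes (both adjusted p = 0.0162 with an estimated correlation) and endothelial markers (adjusted p = 0.0179 with an estimated correlation), and fatty acid oxidation did not (adjusted p = 0.0623 with an estimated correlation).

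Of the other lists that passed, immune ones were higher with VEGF-B in VEGFR1-deleted hearts at the preset correlation and not with an estimated one. Interferon response had a median of 0.64, and 3 of 22 rose (12 adjusted over the list alone), as for Oasl2 (0.96). Antigen presentation had one of 0.57 (1 of 14 rose, H2-D1 by 0.67), macrophage markers one of 0.42 (2 of 12 rose, Lgals3 by 1.09 and Adgre1 by 0.85), T and NK cell markers one of 0.45 (1 of 9 rose, Ccl5) and neutrophil markers one of 0.83 (3 of 6 rose, S100a8, S100a9 and Il1b). For these 5 the adjusted p = 0.170, 0.434, 0.354, 0.322 and 0.0702 with an estimated correlation, and H2 genes are near-identical, so their probes may read more than 1 gene. VEGFR1del_VEGFB replicate 3 had the highest scores of its group for antigen presentation and for T and NK cells, and without it the medians were 0.29 (adjusted p = 0.00107) and 0.14 (adjusted p = 0.0279). Of the vascular lists, Notch pathway (0.40, 3 of 11 rose), paracrine factors (0.29, 3 of 11), arterial (0.32, 2 of 7) and venous endothelium (0.37, 1 of 6) had an adjusted p = 0.0702 with an estimated correlation. Pericyte markers had a median of 0.36, and 3 of 10 rose (adjusted p = 0.116 with an estimated correlation). Cell cycle (0.26, none of 21, adjusted p = 0.0702 with an estimated correlation) and immediate early genes (0.42, none of 14, adjusted p = 0.528 with an estimated correlation) held no gene past the threshold. The immediate early call was lost without VEGFR1del_Scramble replicate 1 or 2 or VEGFR1del_VEGFB replicate 2 (adjusted p up to 0.115), and that of T and NK cells without the library labelled VEGFR1del_Scramble replicate 3 (0.0782). Of the VEGF ligands and receptors, Nrp1 rose by 0.48 (SE 0.11, adjusted p = 0.0258). Flt1 gave -0.21 (SE 0.58, adjusted p = 0.875), and 0.87 (adjusted p = 0.0110) without that library.

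Here too the count changed with an array left out, where power is lost as well. It was 40 and 28 without VEGFR1del_Scramble replicates 1 and 2, and 238, 404 and 283 without VEGFR1del_VEGFB replicates 1, 2 and 3. Of 51 calls named for this comparison, 9 held without any 1 array, namely Esm1, Stc1, Sdf2l1, Pdia4, Col18a1, Lman1l, Ces1d, Kcnv2 and Slc27a1. No fit with the set as a fixed block can be had, because no set holds both VEGFR1del_VEGFB arrays and scramble arrays, so VEGF-B and the set cannot be told apart in this comparison. The share of called genes that were higher depended on the scaling of the arrays, at 61.1% here, 95.9% with median scaling and 86.6% on the authors' values. Median scaling moved the median of all genes by 0.12, and relative to that the fatty acid oxidation list at -0.40 lay lower still.

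**Figure D2:**
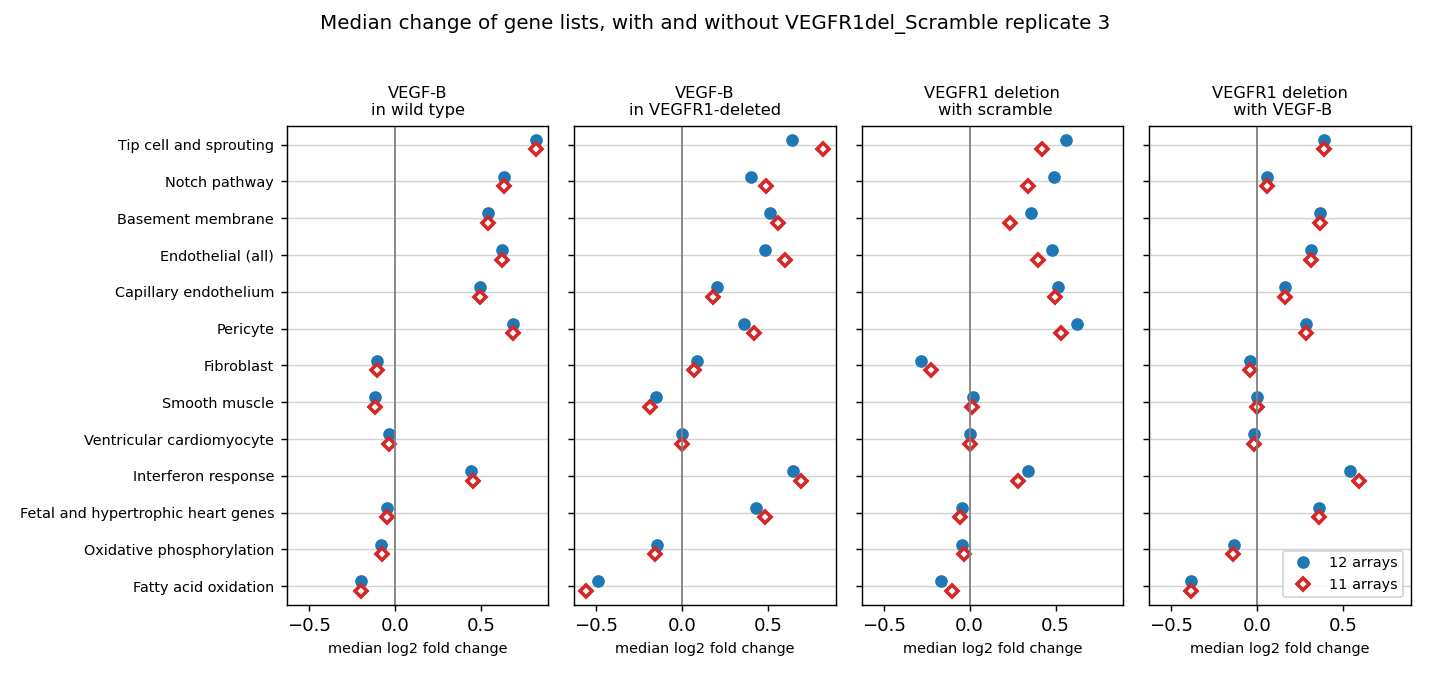
Median log2 fold change of 13 gene lists (horizontal axis) in 4 comparisons, on 12 arrays (blue circles) and on 11 arrays without the library labelled VEGFR1del_Scramble replicate 3 (open red diamonds). The tip cell list lies at 0.82, 0.64, 0.56 and 0.39 on 12 arrays and fatty acid oxidation at -0.20, -0.49, -0.17 and -0.39.

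The effect of the deletion without VEGF-B was asked in VEGFR1del_Scramble (n = 3) against WT_Scramble (n = 3). Esm1 was higher by 2.16 (SE 0.20, adjusted p = 0.00103, limma), and Ssu2 (1.40, SE 0.17), Ccn5 (1.39, SE 0.18), Cxcr4 (1.33, SE 0.16), the lymphocyte and endothelial GTPase Gimap6 (0.86, SE 0.12) and the pericyte genes Kcnj8 (0.83, SE 0.12) and Vtn (0.72, SE 0.11) rose with it. Angptl4 fell by 2.09 (SE 0.30, adjusted p = 0.0213). These 8 genes were the ones called, 7 higher and 1 lower, and 1617 genes had an unadjusted p under 0.05. Without the library labelled VEGFR1del_Scramble replicate 3, 9 features were called, 4 of them among the 8. Esm1 (2.01), Cxcr4 (1.46), Ssu2 (1.20) and Ccn5 (1.14) kept their calls, Flt1 gave -2.54 (adjusted p = 3.12e-05), against -1.46 (SE 0.61, adjusted p = 0.377) with it, Csprs, Dip2c, Ern1 and an unnamed probe (ILMN_2476405) were the others, and Angptl4 gave -2.02 (adjusted p = 0.0833). Stc1 (1.34, adjusted p = 0.0521), Csprs (1.14), Tmem255b (0.88), Tcim (0.87), Tmc6 (0.85), Higd1b (0.77), Mcf2l (0.73), Notch4 (0.71), Gpihbp1 (0.71), Emcn (0.70), Samd9l (0.61) and Ica1 (0.52) came next, with an adjusted p of 0.0521 to 0.0550.

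Several vascular lists were higher in deleted hearts at the preset correlation, while arterial endothelium (0.06, adjusted p = 0.115), lymphatic endothelium and smooth muscle did not pass. Capillary endothelium had a median of 0.51 (5 of 7 rose adjusted over the list alone, none over all genes) and was the list that held with an estimated correlation on 12 arrays (adjusted p = 0.0401). On the other 11 arrays 4 lists held, capillary endothelium, tip cell genes and endothelial markers (each adjusted p = 0.0252 with an estimated correlation) and pericyte markers (adjusted p = 0.0407 with an estimated correlation). Tip cell genes had a median of 0.56 (0.42 without the doubted library), and 2 of 18 rose (15 adjusted over the list alone). Pericyte markers had a median of 0.62 (0.53 without it), and 2 of 10 rose (9 adjusted over the list alone). Venous endothelium had a median of 0.28. For these 3 the adjusted p = 0.0511 with an estimated correlation on 12 arrays. Endothelial markers had a median of 0.48 and Notch pathway one of 0.49, with 15 of 22 and 7 of 11 genes past when adjusted over the list alone and none over all genes (adjusted p = 0.0635 with an estimated correlation). Basement membrane (0.36) and cell cycle (0.21) also passed (adjusted p = 0.0940 with an estimated correlation), as did interferon response (0.34, 0.463 with an estimated correlation), antigen presentation (0.32, adjusted p = 0.750 with an estimated correlation) and atrial cardiomyocyte markers (0.30, adjusted p = 0.154 with an estimated correlation). Fibroblast markers were lower, with a median of -0.28 and Pdgfra at -0.63 (adjusted p = 0.0680 with an estimated correlation), and so were fatty acid oxidation genes, at -0.17 (adjusted p = 0.463 with an estimated correlation). Oxidative phosphorylation and tricarboxylic acid cycle passed below 0 with median scaling, on the authors' values and without background correction (adjusted p up to 0.0312), and not here. Without the library labelled VEGFR1del_Scramble replicate 3 the calls of fatty acid oxidation (-0.10, adjusted p = 0.0576), antigen presentation (0.0786) and atrial markers were lost, and circadian clock (0.55, adjusted p = 0.00249) and macrophage markers (-0.27, adjusted p = 0.0310) passed. Antigen presentation was also lost without WT_Scramble replicate 2, and atrial markers without any of 7 libraries, the WT_Scramble replicate 3, VEGFR1del_Scramble replicates 1 and 3, both WT_VEGFB and VEGFR1del_VEGFB replicates 3 and 4 (adjusted p up to 0.116).

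All arrays of this comparison but the doubted library lie in normalization set 1. On those 5 arrays 5 features were called, Flt1 (-2.54, SE 0.14, adjusted p = 0.000517), Esm1 (2.01, SE 0.17, adjusted p = 0.00998), Cxcr4, Csprs and the probe ILMN_2476405, and 14 lists passed, with medians of 0.42 for tip cell genes, 0.53 for pericyte markers and -0.22 for fibroblast markers. Fatty acid oxidation (-0.10, adjusted p = 0.0449) and antigen presentation (0.23, adjusted p = 0.00103), lost on 11 arrays, were among the 14. The set as a fixed block on 8 arrays also gave 5, with Dip2c (-0.96) in the place of Csprs. The count of genes was 16, 4 and 4 without WT_Scramble replicates 1, 2 and 3 and 14 and 21 without VEGFR1del_Scramble replicates 1 and 2, and of the 8 calls those of Esm1 and Cxcr4 held without any 1 array. Without WT_Scramble replicate 2 the other calls were Cntn3 (-0.89) and Rbp7 (0.96), and without replicate 3 Angptl4 (-2.35) and Ssu2 (1.55).

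The effect of the deletion under VEGF-B was asked in VEGFR1del_VEGFB (n = 4) against WT_VEGFB (n = 2). No gene passed (limma, with 1572 at an unadjusted p under 0.05), Flt1 included at -2.17 (SE 0.65, adjusted p = 0.261). Flt1 was lower on all 4 deleted arrays than on both wild-type arrays. The spread that the model shares over the groups includes that of the library labelled VEGFR1del_Scramble replicate 3. Without that library, which is in neither group, Flt1 passed (-2.17, adjusted p = 0.000102) with 5 more, Dip2c (-1.09), Nmrk2, a kinase of NAD synthesis (-0.81), Csprs (1.49), Plk2 (0.88) and the probe ILMN_2476405. Without VEGFR1del_VEGFB replicate 1, 1 feature passed, the unnamed probe ILMN_2772264 (1.15). Other genes of small p that did not pass were Slc13a4, Tnfrsf22, Tcirg1, Samd9l, Rab27a and Klf6, between 0.54 and 0.75, and Gp5, Acadl, Mpig6b, Fyco1, Armh4, the fatty acid transporter Slc27a1, Tafa5, Ces1d, Adhfe1 and Lgals4, between -1.22 and -0.56.

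By list, 15 passed and none with an estimated correlation on 12 arrays. On the 11 arrays without the doubted library, tip cell, basement membrane and endothelial genes held (each adjusted p = 0.0418 with an estimated correlation). Fatty acid oxidation had a median of -0.39, with all 21 genes below 0 and 14 past when adjusted over the list alone (none over all genes). Oxidative phosphorylation (-0.14) and tricarboxylic acid cycle (-0.18) were lower too. Tip cell (0.39), basement membrane (0.37), endothelial (0.32), venous (0.28), interstitial matrix (0.27), cell cycle (0.24) and fetal heart genes (0.36) were higher. For all of these the adjusted p = 0.174 with an estimated correlation on 12 arrays. Interferon response was higher, with a median of 0.54, all 22 genes above 0 and 6 past when adjusted over the list alone (adjusted p = 0.185 with an estimated correlation). Unfolded protein genes (0.30), pericyte markers (0.29), antigen presentation (0.32) and T and NK cell markers (0.26) were higher, with adjusted p = 0.175, 0.283, 0.575 and 0.334 with an estimated correlation. Calls were lost for cell cycle without WT_VEGFB replicate 1 or VEGFR1del_VEGFB replicate 3 (adjusted p up to 0.0940), and for the tricarboxylic acid cycle without WT_VEGFB replicate 2 (0.0786). Antigen presentation (up to 0.808) and T and NK cells (up to 0.186) lost theirs without WT_VEGFB replicate 2 or VEGFR1del_VEGFB replicate 3. The WT_VEGFB arrays are in set 2 and the VEGFR1del_VEGFB arrays in set 3, so set and genotype cannot be told apart here.

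Whether the effect of VEGF-B differed between the genotypes was asked by the interaction. No single gene passed (limma, 718 at an unadjusted p under 0.05, and 0 and 813 without the doubted library), and 1 feature, the probe ILMN_2772264 (1.26), did without VEGFR1del_VEGFB replicate 1. Genes with the smallest p included Esm1 (-1.22, SE 0.29), Ano10 (-1.03) and the water channel Aqp1 (-0.75) below 0, and Zbtb38 and Lman1l (both 1.14, SE 0.24 and 0.27) and Rhou (0.92) above 0, each at an adjusted p of 0.975. The WT_VEGFB arrays are in set 2 and the VEGFR1del_VEGFB arrays in set 3, so a difference between these sets enters the interaction and cannot be told apart from the genotype. By list, 10 passed and none with an estimated correlation. The response to VEGF-B was more positive in deleted hearts for fetal heart genes (median 0.39, adjusted p = 0.0801 with an estimated correlation), unfolded protein genes (0.28, adjusted p = 0.546 with an estimated correlation), interstitial matrix (0.23, adjusted p = 0.646 with an estimated correlation), fibroblast markers (0.23, adjusted p = 0.331 with an estimated correlation) and interferon response (0.11, adjusted p = 0.813 with an estimated correlation). It was more negative for fatty acid oxidation (-0.22, adjusted p = 0.646 with an estimated correlation), capillary endothelium (-0.33, adjusted p = 0.0801 with an estimated correlation), pericyte markers (-0.35) and Notch pathway (-0.29), both with adjusted p = 0.441 with an estimated correlation, and tip cell genes (-0.27, adjusted p = 0.646 with an estimated correlation). Other lists passed below 0 under another scaling. Oxidative phosphorylation did so with median scaling (-0.21, adjusted p = 6.09e-05), on the authors' values (-0.11, adjusted p = 1.25e-06) and without background correction (-0.05, adjusted p = 0.0152), and the tricarboxylic acid cycle with the first of these (adjusted p = 0.0243) and on the authors' values (adjusted p = 0.00251). Endothelial markers passed with median scaling (-0.18, adjusted p = 0.00968), cyclic loess (-0.15, adjusted p = 0.0481) and on the authors' values (-0.07, adjusted p = 0.0133).

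Without the library labelled VEGFR1del_Scramble replicate 3 the interaction was -0.05 for tip cell genes (adjusted p = 0.263), -0.15 for Notch pathway and -0.32 for fatty acid oxidation. The tip cell call was also lost without WT_VEGFB replicate 2, as were those of Notch pathway and unfolded protein genes (adjusted p up to 0.144 and 0.107). Notch pathway lost its call without WT_Scramble replicate 3, interstitial matrix without WT_Scramble replicate 1 or VEGFR1del_Scramble replicate 1 (up to 0.0811), and fatty acid oxidation without VEGFR1del_Scramble replicate 2 (0.0523). Interferon response lost its call without any of 7 libraries, namely WT_Scramble replicates 1 and 3, VEGFR1del_Scramble replicates 1 and 2, WT_VEGFB replicate 2 and VEGFR1del_VEGFB replicates 2 and 3 (up to 0.653).

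The responses to VEGF-B in the 2 genotypes resembled each other across genes. The log2 fold changes had a Pearson r of 0.591 and a Spearman rho of 0.521 over 14240 genes, which are not independent replicates, and the comparisons share no array. Of the 284 genes called in wild type, 281 changed with the same sign in deleted hearts, and 132 were called higher and 9 lower in both, where independent lists would share 7.01 and 0.627. Among them were Esm1, Stc1, Sparc, Pdgfrb and Mcam above 0 and Ucp3 and Pdk4 below. On 11 arrays r was 0.595. The change with VEGF-B in wild type also resembled the change with the deletion (r = 0.732, covariance 0.0428), but these comparisons share the WT_Scramble arrays, and unchanged groups simulated against the same controls gave r = 0.448 and a covariance of 0.0120. Without the doubted library r was 0.599 against 0.401, and the covariance 0.0355 against 0.0115. The sets named above run along with the virus, so an effect common to the arrays of sets 2 and 3 would add to the first correlation.

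Of the 40 measured lists, 24 passed in at least 1 comparison and 16 in none. Ventricular cardiomyocyte markers stayed between -0.03 and 0.05 over the 5 comparisons (lowest adjusted p = 0.590). Smooth muscle (medians -0.15 to 0.02, lowest adjusted p = 0.0907), lymphatic endothelium (-0.29 to 0.03, 0.431), adipocyte (-0.17 to -0.02, 0.431), skeletal muscle (-0.12 to 0.08, 0.561), Schwann cell (-0.21 to 0.09, 0.311), thymus (-0.16 to 0.11, 0.540), erythroid (-0.14 to 0.06, 0.228) and B and plasma cell markers (-0.12 to 0.51, 0.159) did not pass. Neither did ribosomal protein (-0.01 to 0.07, 0.118), glycolysis (-0.09 to 0.10, 0.108), hypoxia (-0.10 to 0.15, 0.318), circadian clock (-0.02 to 0.26, 0.223), fatty acid uptake (-0.07 to -0.02, 0.350), ErbB (-0.10 to 0.09, 0.411), and VEGF ligand and receptor genes (-0.09 to 0.03, 0.250). Of these 16 lists, 9 passed under at least 1 alternative. With median scaling, ventricular cardiomyocyte markers gave -0.21 for the deletion under VEGF-B (adjusted p = 0.000167), -0.17 in the interaction (adjusted p = 0.00727) and -0.03 with VEGF-B in deleted hearts (adjusted p = 0.0112), and smooth muscle gave -0.06 there (adjusted p = 0.0124). Glycolysis gave -0.16 for the deletion with scramble (adjusted p = 0.0124) and -0.19 with VEGF-B (adjusted p = 0.0120), where erythroid markers gave -0.39 (adjusted p = 0.0272). On the authors' values glycolysis also passed in these comparisons (adjusted p = 0.0427 and 0.0168). With VEGF-B in deleted hearts it gave 0.01 on those values (adjusted p = 0.0474), below the median of all genes, 0.06, and -0.03 here. Smooth muscle and ventricular cardiomyocyte markers passed there too (both adjusted p = 0.0256), and ribosomal protein genes for the deletion with scramble (0.08, adjusted p = 0.0258, and 0.06 without background correction, adjusted p = 0.0269). Circadian clock, VEGF ligand and receptor, B and plasma cell and skeletal muscle lists passed with an array left out, as did smooth muscle and erythroid markers. Within fatty acid uptake, where the list did not pass, Angptl4 fell in wild type as given above, Fabp5 rose there (0.90), and Slc27a1 (-0.76) and Plin5 (-0.56) fell with VEGF-B in deleted hearts.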

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

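The tests that weigh explanations of the first 3 patterns below were chosen after the results were seen. The calls of genes and lists, the counts of other splits and the tests for an array far from the others were planned. H2-Ab1, Cd3g and Ciita entered the last of these after their values were seen.

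A first pattern is the high Flt1 signal of the library labelled VEGFR1del_Scramble replicate 3. The authors' normalization did not enter these values, which come from the deposited signals before normalization. A wrong label on a WT_VEGFB heart cannot be told apart from a scramble heart with intact Flt1, by a wrong label or a deletion that did not take place. Of the 113 other features that part the genotypes on the other 11 arrays, 88 (77.9%) lay nearer WT_VEGFB than VEGFR1del_Scramble replicates 1 and 2, and 8.85% nearer WT_Scramble than those. But VEGF-B in wild type moved 109 of the 113 in the direction of the deletion, so a shift of the library along that direction gives such shares with either. The features it moved the other way were ILMN_2476405, Cbx7, Ap3b2 and Uba6. On the library each of them lay nearer both wild-type groups than VEGFR1del_Scramble replicates 1 and 2. They part wild-type-like from deleted arrays, and do not tell these explanations apart. The library had a position of 0.771 from WT_Scramble (0) to WT_VEGFB (1), and VEGFR1del_Scramble replicates 1 and 2 lay at 0.434 and 0.502. Left-out WT_Scramble arrays lay at 0.162 to 0.327, and left-out WT_VEGFB arrays at 0.627 and 0.630. Each left-out array was placed on an axis drawn without it, which for WT_VEGFB ended at the 1 other array of that group. These positions are not on the scale of the library, so it cannot be placed beyond or short of the WT_VEGFB arrays. The library's normalization set holds no other scramble array, and a difference between sets may have moved it. The test against WT_VEGFB was added after the one against WT_Scramble was seen, and the heart was not moved to another group.

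A second pattern is the number of genes called for VEGF-B. The authors' normalization of 3 separate sets did not enter these counts, since the signals were normalized here over all 12 arrays at once. A difference between batches of arrays that follow those sets cannot be told apart from the virus. With the set as a fixed block 3 genes were called in wild type, but that fit links the sets through the library labelled VEGFR1del_Scramble replicate 3 alone, whose label is in doubt, so it decides nothing. An effect of VEGF-B itself stays open beside it.

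The last pattern weighed is tip cell genes higher and fatty acid oxidation genes lower with VEGF-B. A smaller share of cardiomyocytes is argued against as the whole cause of the fall in oxidation genes. Their score minus that of 7 cardiomyocyte markers changed by -0.38 (exact two-sided permutation within genotype, p = 0.00286, the smallest that 350 arrangements can give, and 0.0286 within deleted hearts). These markers had a mean log2 signal within the range of the oxidation genes, 6.15 to 14.10, and were not matched to them more closely. The markers alone changed by -0.10 (exact p = 0.0371, and 0.171 within deleted hearts). A larger share of endothelial cells is argued against as the whole cause of the rise in tip cell genes, over both genotypes together. Their score minus that of 22 endothelial markers changed by 0.27 (exact p = 0.00286, and 0.0571 within deleted hearts). Unlike the cardiomyocyte markers, the endothelial markers were not restricted to the signal range of the list, so a difference in signal may enter this change. The endothelial markers themselves rose by 0.51 (exact p = 0.00286), and pericyte markers minus these changed by 0.03 (exact p = 0.640), while smooth muscle markers minus these changed by -0.69 (exact p = 0.00286) and fibroblast markers by -0.47 (exact p = 0.00571, and 0.114 within deleted hearts). A larger share of endothelial cells stays open for part of the rise. On 11 arrays the changes were -0.43 and 0.29, each at the smallest exact p that 150 arrangements can give, 0.00667. A change in the state of the cells, in the share of endothelial subtypes, and a difference between the sets of arrays all stay open.

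For VEGF-B in deleted hearts, 1 of the 35 splits of the 7 arrays, the real one, gave as many as 656 genes, and the highest other split gave 5. This argues against chance, at the smallest share that 35 splits can give. This split also parts set 3 from sets 1 and 2. For the deletion with scramble virus the real split of 6 arrays gave 8 genes and the highest of the other splits 0, and the 10 splits, of which 1 gave 8 genes, are too few for a share under 0.05.

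In the 4 VEGFR1del_VEGFB arrays, 157 values were tested for an array far from the other 3, and 13 stood out. For values chosen without regard to the arrays, chance gives about 1 in 20. The values tested were those of genes named here and the list scores. H2-Ab1, Cd3g and Ciita were named after their values were seen, and 2 of the list scores hold them. The 13 can therefore not be set against that share. The measure is the gap to the nearest array over the range of the group. VEGFR1del_VEGFB replicate 3 was high for H2-Ab1 (0.939), Cd3g (0.861), Ciita (0.838), Plin5 (0.900), the antigen presentation score (0.874) and the T and NK cell score (0.882). Replicate 4 was low for Adamtsl2 (0.857) and high for Flt4 (0.902) and Spon2 (0.853). Replicate 2 was low for Cxcr4 (0.866) and high for the thymus score (0.831). Replicate 1 was low for Eci1 (0.902) and high for the fibroblast score (0.961).

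The effect of VEGF-B differed between the genotypes for 10 lists by the interaction at the preset correlation, and for none with an estimated one. The median differences, deleted minus wild type, were 0.39 for fetal heart genes, 0.28 for unfolded protein genes, 0.23 for interstitial matrix, 0.23 for fibroblast markers and 0.11 for interferon response. They were -0.22 for fatty acid oxidation, -0.27 for tip cell genes, -0.29 for Notch pathway, -0.33 for capillary endothelium and -0.35 for pericyte markers. Without the library labelled VEGFR1del_Scramble replicate 3 the tip cell difference was -0.05 and did not pass (adjusted p = 0.263), and the others passed, with -0.15 for Notch pathway, -0.25 for pericyte markers, -0.32 for fatty acid oxidation and 0.21 for interferon response. In all 10 lists passed without that library, so a list not named here was gained. Any difference between normalization sets 2 and 3 enters these values, so it cannot be told apart from the genotype.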

How the results depend on the processing

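The fits with the authors' normalization set as a block or with set 1 alone, and the 11-array fit as a second account of each comparison, were chosen after the data were seen. All other alternatives were planned. The chip as a block was not run, since the files do not give it. Signal over background limits what can be seen for genes near the floor, such as Kdr. Where a cause is not given, the cause was not tested.

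Counts are given in the order VEGF-B in wild type, VEGF-B in deleted hearts, the deletion with scramble and the deletion with VEGF-B, against 284, 656, 8 and 0. No background correction gave 430, 1069, 91 and 68, an offset of 50 gave 439, 1019, 107 and 26, the authors' processed values 547, 1770, 95 and 93, and a trended and robust variance 491, 1030, 194 and 78. An adjusted p under 0.10, a looser threshold by construction, gave 555, 1307, 176 and 2. Median scaling gave 553 and 1050 for VEGF-B and 4 for the deletion with VEGF-B. Only the groups compared, with fewer arrays to estimate the spread, gave 175, 176, 1 and 3. Array weights gave 444 for VEGF-B in wild type and 10 for the deletion with VEGF-B. For VEGF-B in deleted hearts a log2 fold change of at least 0.5 gave 425 and the replicate block 370, though replicate numbers do not pair the hearts. For the deletion with scramble, cyclic loess gave 54, every probe 13, the mean of probes 19 and the strict filter 99, which gave 7 for the deletion with VEGF-B. The set as a fixed block gave 3 for VEGF-B in wild type and 5 for the deletion with scramble, and set 1 alone also 5. With each array left out in turn the counts ran from 4 to 397, 28 to 1031, 4 to 21 and 0 to 6, and from 0 to 1 for the interaction, which gave 0 under all other alternatives.

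The correlation of the VEGF-B responses in the genotypes, 0.591, was 0.697 without background correction, 0.689 on the authors' values, 0.693 with the strict filter and 0.730 on the genes above the middle of the mean signal, but 0.566 on every probe and 0.539 without a filter, and 0.514 to 0.595 with an array left out. That of VEGF-B with the deletion, 0.732, ran from 0.599 to 0.777 with an array left out and from 0.695 to 0.826 otherwise. Of 98 calls of named genes 11 held under every alternative counted, and of 75 list calls 6 did. Of the 75, 54 held with each array left out, and 60 under every other alternative counted that is not the estimated correlation or fry. Not counted were the set as a fixed block, set 1 alone, the other thresholds and, for lists, every probe. With the set as a fixed block 10 lists passed for VEGF-B in wild type, against 16 in the main fit. Calls lost were those of venous endothelium (camera adjusted p = 0.0523), immediate early genes (0.0649, median -0.45) and interferon response (0.0655). Lost too were paracrine factors (0.152), neutrophil markers (0.152), cell cycle (0.376), interstitial matrix (0.447) and fatty acid oxidation (0.790). Circadian clock (median 1.06, adjusted p = 8.92e-06) and VEGF ligands and receptors (-0.36, adjusted p = 0.0476) were gained. These rest on the linking library, whose label is in doubt. Over the alternatives counted, named genes stayed on the same side of the threshold in 7261 values, lost the call in 447 and gained one in 290. Lists did so in 5093, 170 and 87. A change of sign where neither fit passed the threshold was counted as staying on the same side. The sign turned past a threshold for Flt1 with VEGF-B in deleted hearts, from -0.21 to 0.87 without the library labelled VEGFR1del_Scramble replicate 3, whose own signal of 11.56 sets the difference, and the range with an array left out was -0.82 to 0.87.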

Other observations

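The probe with the clearest difference between the genotypes besides Flt1 has no gene symbol here. ILMN_2476405 gave a log2 signal of 4.66 in WT_Scramble, 4.60 in WT_VEGFB, 8.86 in VEGFR1del_Scramble replicates 1 and 2, 9.41 in VEGFR1del_VEGFB and 4.47 in the library labelled VEGFR1del_Scramble replicate 3. Csprs was higher in deleted hearts in each comparison of genotypes, by 1.14 with scramble and 1.49 with VEGF-B, and Dip2c was at -0.69 and -1.09, and neither passed on 12 arrays. These features were picked after their values were seen, and no test was run of what they are.

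The circadian clock list did not pass in any comparison on 12 arrays. Without the library labelled VEGFR1del_Scramble replicate 3 its median was 0.55 with the deletion under scramble virus, and the output genes Ciart (1.86, adjusted p = 0.201), Per2 (1.03) and Dbp (0.86) lay above 0 while the activator Arntl lay below it (-0.74), none past the threshold. The mean score of the list was -0.11 to 0.17 on the WT_Scramble arrays, 0.26 and 0.65 on VEGFR1del_Scramble replicates 1 and 2, and -0.30 on that library. It was 0.25 and 0.37 on the WT_VEGFB arrays and 0.32 to 0.60 on the VEGFR1del_VEGFB arrays. A score above the WT_Scramble range was thus not particular to the deletion. The times of day of collection are not in the labels.

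Genes of antigen presentation and of T cells stood apart on VEGFR1del_VEGFB replicate 3. Ciita, the regulator of MHC class II genes, gave 5.68 there and 4.49 as the mean of the other 3 arrays of the group, and the T cell receptor component Cd3g gave 5.99 and 4.66. H2-Ab1 gave 11.2 and 9.72. The same array had the highest score of both lists, 1.62 for antigen presentation and 1.16 for T and NK cells, where the next highest arrays of its group had 0.61 and 0.37. These 3 genes were named after their values were seen.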
